A study of Homo sapiens with 15 samples.

How the data were processed

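Total RNA of 2 human prostate cancer cell lines was measured on a 3' expression array, with 1 biotin-labelled sample on each of 15 arrays. PC3 cells carried a control short hairpin RNA (shRNA) or 1 of 2 shRNAs against CHD1, and LNCaP cells were controls or a CHD1 knockout made by genome editing. Each of the 5 groups held 3 arrays, taken from the titles in the labels. The titles call the second PC3 reagent a CHD1 shRNA, while its characteristics name shCHD2, and the titles were followed. The labels number the replicates but do not say whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

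The values are the intensity of each probe set on a linear scale, as deposited by the authors, with 1 column per sample and no pooled replicates. The submitters' processing notes name MAS5 without a version; the background correction, summary and scaling steps are not given in the sources used here. The values themselves were checked. Trimmed means differed between arrays (77.5 to 86.4), and identical values recurred between arrays of the same line (2.22% to 6.07% of probe sets between arrays of the same PC3 group) but at 0 probe sets between PC3 and LNCaP arrays. A global scaling of each array to 1 target would not give this pattern, and the lines appear to have been normalised separately, so a level in PC3 is not strictly comparable with a level in LNCaP. The authors' scaling was kept, and all changes were computed within a line.

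The table held 54675 probe sets. The platform annotation gave 1 gene symbol for 41097 of them, several for 1801 and none for 11777; probe sets with several symbols or none were not analysed here. Symbols were updated by gene ID through a RefSeq table of assembly GRCh38.p14, which matched 41043 probe sets and served only for names, gene span and gene neighbours. Of the probe sets of a gene, the one with the highest mean log2 value over the 15 arrays represented it, which gave 19775 genes; genes without a probe set of their own symbol were not analysed here. Values were tested as log2(intensity + 16), so folds of dim genes are understated. Folds of genes are given on this tested scale and are smaller than the ratios of the intensities printed beside them. Genes were tested when their mean lay above the 40th percentile of genes over the arrays of the fit, which left 11865 genes in each line and 10686 in both. Group means of the median intensity were 16.1 to 17.3, and 32.3% to 35.7% of genes lay under an intensity of 16 on an array. The number of arrays limits the precision.

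Differential expression was computed with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend), two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The 9 PC3 arrays and the 6 LNCaP arrays were fitted apart, and the difference between the line effects was an interaction contrast over all 15 arrays. Errors of log2 changes are standard errors from limma, and errors of intensities are SDs of 3 arrays. Overlaps between the lines were tested with Fisher's exact test, and measures of array quality with exact permutation tests. For the effects of the 2 PC3 reagents, which share their control arrays, unchanged groups were simulated with independent noise, the shared control group included. Gene lists, 26 in all, were tested with camera at its preset correlation of 0.01 where at least 5 members were tested; camera with an estimated correlation and fry, which tests a list against no change rather than against other genes, were alternatives. NF-kB is a theme the study is known to have reported, and its list was written from general knowledge. List tests of shRNA 2 against shRNA 1 and of the difference between lines were added after the data were seen.

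The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. Under the rule, a gene qualified when it was called and the replicate values of the compared groups did not overlap. It named CHD1 throughout; the 12 genes that rose most and the 12 that fell most in PC3, ranked by the smaller change of both reagents; the 12 and 12 in LNCaP; up to 4 members with the smallest adjusted p of each list past its test; up to 8 NF-kB response genes per line; 4 and 4 genes in the test between the reagents and in the test between the lines; and 6 and 6 genes changed the same way in both lines. Genes on the Y chromosome are given as counts only. The alternatives were pseudocounts of 1 and 64, quantile normalisation, the mean of all probe sets of a gene, probe sets without the _x_at and _s_at endings, no level filter or the 60th percentile, eBayes without trend, 1 fit for all arrays, the replicate number as a block and each array left out in turn. A minimum fold of 2, arrays centred on their median and a correction for gene span were added after the data were seen.

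The pipeline was tested on simulated data built from the real arrays' means and spread, with 200 genes changed by known amounts. At log2 changes of 0.5, 1 and 2, 100% of planted genes were called for each shRNA, for their mean and for the knockout. At 0.25, limma called 77.6% for shRNA 1, 59.2% for shRNA 2, 83.7% for their mean and 90% for the knockout. Of 11677 unchanged genes, 15, 17 and 19 were called in the PC3 comparisons, and of 11671 in LNCaP, 12 were called. In the same check, 0 lists without planted genes were called. The simulated genes varied independently, so this does not test the list calls for genes that vary together. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.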

Results

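The series profiled what loss of CHD1, a chromodomain helicase that remodels nucleosomes and is often deleted in prostate cancer, does to gene expression in 2 prostate cancer cell lines. PC3, derived from a bone metastasis and lacking androgen receptor signalling, carried a control shRNA or 1 of 2 CHD1 shRNAs. LNCaP, an androgen-responsive line from a lymph node metastasis, was compared with a CHD1 knockout. Each of the 5 groups held 3 arrays, and group means of the median intensity lay between 16.1 and 17.3. Replicates within a group correlated at 0.997 or above across all probe sets. Arrays of the PC3 control correlated with those of either shRNA at 0.940 to 0.959, the arrays of the 2 shRNAs with each other at 0.977 to 0.979, and LNCaP control with knockout at 0.994 to 0.995.

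CHD1 itself fell in the knockout but hardly in PC3. In LNCaP, CHD1, by the probe set that stands for it, had an intensity of 182 ± 4.28 (SD, n = 3) in the control and 82.4 ± 3.58 in the knockout. On the tested scale this was a 2.01-fold fall (limma adjusted p = 9.8e-10). Editing need not lower an mRNA, and a probe outside the edited part would check nothing, but here both CHD1 probe sets were lower. In PC3 the control gave 28.9 ± 1.68, the arrays labelled CHD1 shRNA 1 28.7 ± 2.07 and those labelled CHD1 shRNA 2 22.5 ± 3.03. The change was -0.01 (SE 0.07, adjusted p = 0.93) on the log2 scale for shRNA 1, and CHD1 fell by 0.23 (adjusted p = 0.0048) for shRNA 2. The second CHD1 probe set gave 24.6 ± 1.92, 29.4 ± 2.81 and 21.4 ± 2.52 in the same order. CHD1 lay at the 43.3 percentile of gene levels in PC3 and at the 68.5 percentile in LNCaP. The small shRNA 1 change depended on the setting: it was 0.08 (adjusted p = 0.18) with the mean of both probe sets and -0.28 (adjusted p = 9.0e-04) with the trend on gene span removed, a correction added after the data were seen. The target check thus lends the label of shRNA 1 no support in the main setting. CHD1 lies near background in PC3, so the check cannot tell a missed knockdown from a wrong label. For shRNA 2 the log2 change ranged from -0.48 to -0.10 over 19 alternatives. Both PC3 groups are named by their labels wherever a direction is given below. CHD2, the gene in the characteristics of the second reagent, rose by the probe set that stands for it, 1.57-fold in the arrays labelled shRNA 2 and 3.08-fold in those labelled shRNA 1, but its 6 probe sets ranged from -0.19 to 0.65 and from -0.12 to 1.62 on the log2 scale.

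**Figure D1:**
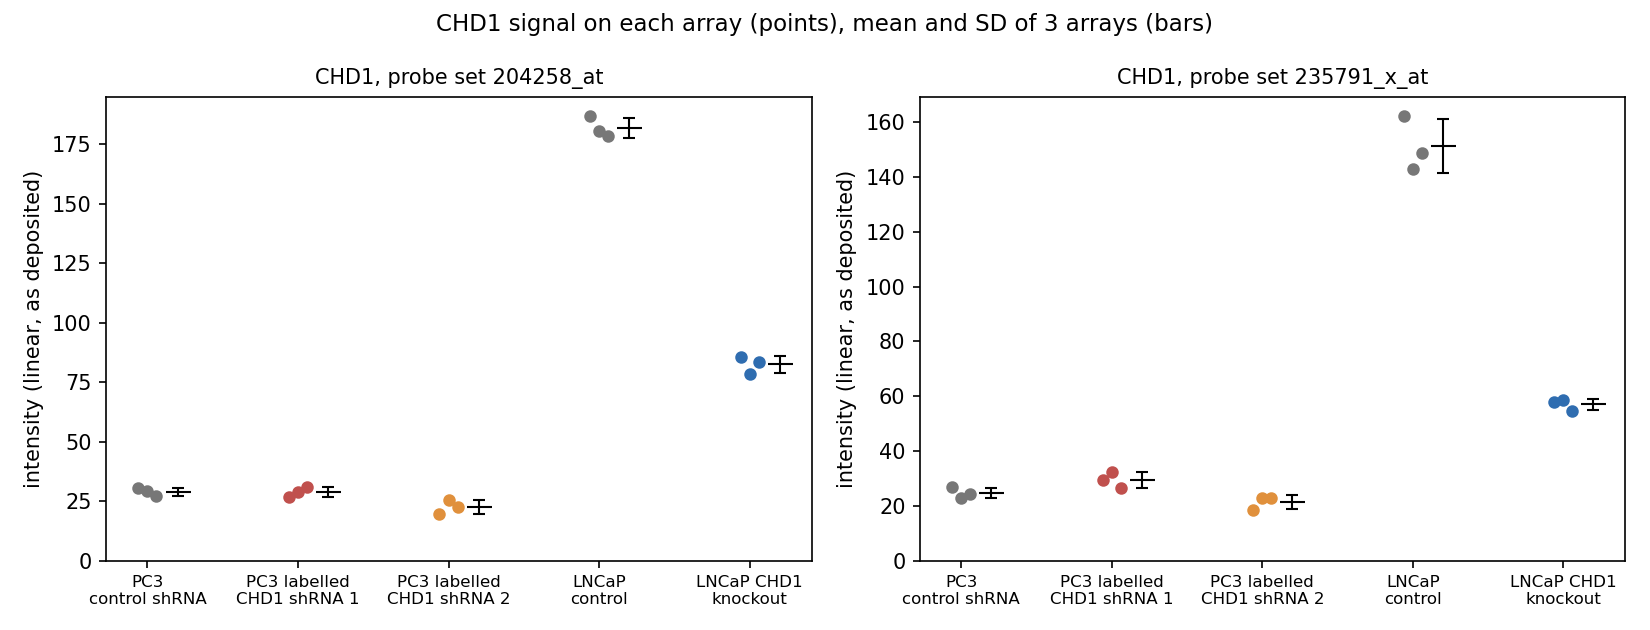
CHD1 intensity (linear scale, vertical axis) on each of the 15 arrays for both CHD1 probe sets, by group (horizontal axis), with bars for the mean and SD of 3 arrays. With the first probe set, the LNCaP knockout averages 82.4 against 182 in its control, and the PC3 groups lie at 28.9, 28.7 and 22.5.

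The control RNAs spiked into the samples also differed between the PC3 groups. The mean log2 intensity of the 12 poly-A spike probe sets, which report RNA added before labelling, was 7.87 ± 0.09 (SD, n = 3) in the PC3 control arrays, 6.97 ± 0.15 in those labelled shRNA 1 and 6.97 ± 0.17 in those labelled shRNA 2. The shRNA arrays were thus 1.86-fold lower, with an exact two-sided permutation p of 0.0119, the smallest that 84 splits can give (0.0833 after Benjamini-Hochberg over 21 tests). In LNCaP the means were 7.05 and 6.96, with an exact p of 0.3; the hybridisation spikes differed by -0.10, the GAPDH 3'-to-5' log2 ratio by 0.02 and the median intensity by -0.276, each with an exact p of 0.1, the smallest that 20 splits can give (0.191 after Benjamini-Hochberg). The hybridisation spikes, added after labelling, were 1.26-fold lower in the PC3 shRNA arrays, with an exact permutation p of 0.0119 (0.0833 after Benjamini-Hochberg). Every comparison with the PC3 control runs along this difference.

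**Figure D2:**
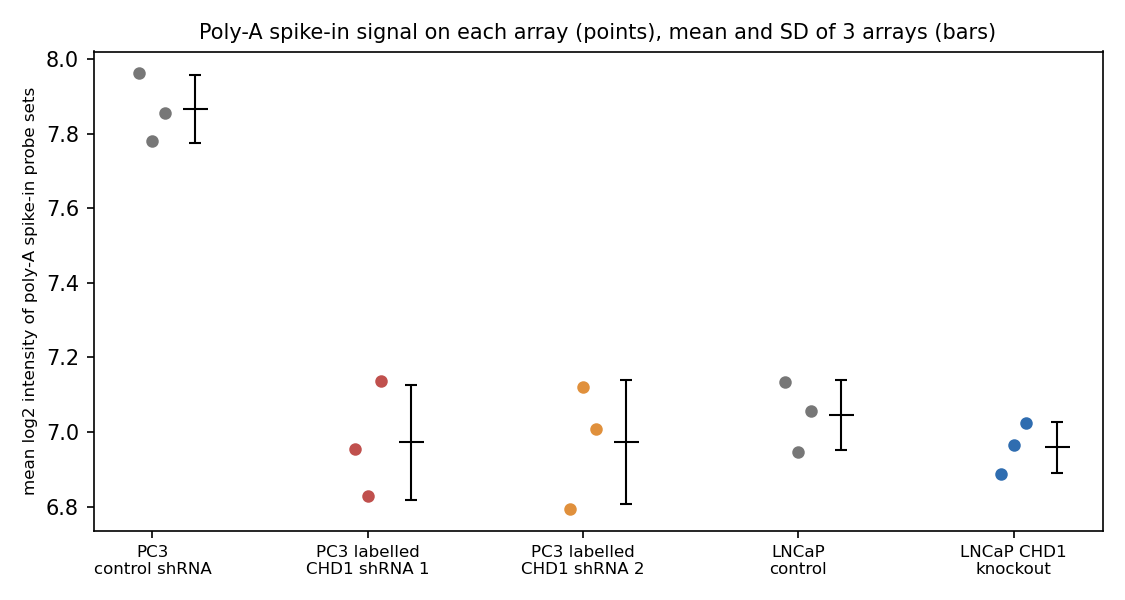
Mean log2 intensity of the poly-A spike-in probe sets (vertical axis) on each array, by group (horizontal axis), with bars for the mean and SD of 3 arrays. The 3 PC3 control arrays average 7.87, and the other groups lie between 6.96 and 7.05.

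The PC3 comparison asked which genes change under 2 independent reagents against CHD1. The 12 genes that fell most in the arrays of both, picked by the size of their change, included 6 CXCL chemokines. CXCL5 fell from 4679 ± 147 (SD, n = 3) to 27.1 ± 3.87 in the arrays labelled shRNA 1 and 31.9 ± 0.755 in those labelled shRNA 2. On the tested scale it was 109-fold and 98-fold lower. S100A8 and S100A9, the subunits of calprotectin, fell 58.3-fold and 35.1-fold for shRNA 1 and 57.2-fold and 35.6-fold for shRNA 2. LCN2, an iron-trapping lipocalin, fell 47.9-fold and 55.8-fold, and complement C3 15.4-fold and 14.5-fold. CXCL1 fell 41.9-fold and 17.4-fold, CXCL2 19.9-fold and 29.7-fold, CXCL3 33.7-fold and 38.2-fold, CXCL6 22.3-fold and 12.1-fold and CXCL8 30.1-fold and 15-fold, as did PTGS2, the inducible cyclooxygenase (31.4-fold and 19.5-fold), and BEX1 (13.0-fold and 12.7-fold).

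The genes that rose most under both PC3 reagents were picked in the same way. PHACTR3, a regulator of protein phosphatase 1, rose from 19.7 ± 3.98 to 1036 ± 43.5 and 429.6 ± 35.3, 29.6-fold and 12.5-fold on the tested scale. ABI3BP, an extracellular matrix protein, rose 14.9-fold and 6.21-fold, and SYT16 10.0-fold and 5.86-fold. CLTC, the clathrin heavy chain, rose from 651 ± 9.68 to 3791 ± 24 and 4105 ± 70.3, and BPTF, the large subunit of the remodeller NURF, rose 6.41-fold with either reagent. TEAD1, a transcription factor of the Hippo pathway, rose 7.23-fold and 6.15-fold, TACC1 6.77-fold and 7.91-fold, PLCB4 7.20-fold and 6.14-fold, ITGB8 5.87-fold and 6.0-fold, BTBD7 6.44-fold and 5.85-fold and CHML 5.71-fold and 7.01-fold. MSI2, an RNA-binding protein, rose 7.08-fold and 5.92-fold, but another of its probe sets went the other way with shRNA 1 (-0.45). Probe sets also disagreed for most of the others: the lowest log2 change for shRNA 1 was -0.10 for BTBD7, -0.06 for CHML, -0.05 for ITGB8, -0.02 for CLTC, 0.01 for ABI3BP and TACC1, 0.20 for BPTF, 0.39 for SYT16 and 0.41 for TEAD1. Among the genes that fell, the weakest probe set of CXCL2 changed by -0.12 and that of S100A8 by -0.91.

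In all, limma called 9980 of 11865 genes for shRNA 1 (4192 higher, 5788 lower) and 9851 for shRNA 2 (4281 higher, 5570 lower). Of these, 7793 changed the same way under both, 3374 higher and 4419 lower, while 949 changed in opposite directions. At a fold of at least 2, a limit added after the data were seen, 1108 were higher and 170 lower under both. The reagents share their control arrays. Across genes, which are not independent replicates, their changes correlated at 0.779 (0.499 with simulated unchanged groups) with a covariance of 0.490 (0.00175 simulated). Simulated unchanged groups gave at most 0 genes called the same way in 20 simulations. They differed by independent noise alone, so they cannot show a shift that all control arrays share, such as that of the poly-A spikes. Independent lists of these sizes would share 1513 higher and 2717 lower genes, and with 3 control arrays part of the excess may come from the shared controls. The median change of all genes was -0.12 for the mean of both reagents, and the changes of gene groups below are to be read against it.

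Genes that respond to NF-kB, a transcription factor of inflammation, fell as a group in PC3. All 23 tested members of the list were lower for the mean of both reagents (10289 genes called in that contrast), with a median of -1.61 (camera adjusted p = 6.6e-10; adjusted p = 0.028 with an estimated correlation). All 23 were also lower when adjusted over the list alone. Besides the chemokines, IL6 fell 11.4-fold for shRNA 1 and 36.2-fold for shRNA 2, and IL1B fell 22.2-fold and 11.5-fold. IER3, an early response gene, fell 2.79-fold and 3.33-fold, and the NF-kB inhibitors NFKBIA and TNFAIP3 fell 4.99-fold and 2.14-fold for shRNA 1 and 3.87-fold and 1.78-fold for shRNA 2, with another probe set of NFKBIA at -0.20 for shRNA 1. The list holds a theme the study is known to have reported, so its direction is not independent of that report. The upstream list of TNF and NF-kB signalling components did not pass its test, with 10 of 20 members higher and 8 lower (adjusted p = 0.40). In the same arrays the poly-A spikes were 1.86-fold lower than in the control.

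**Figure D3:**
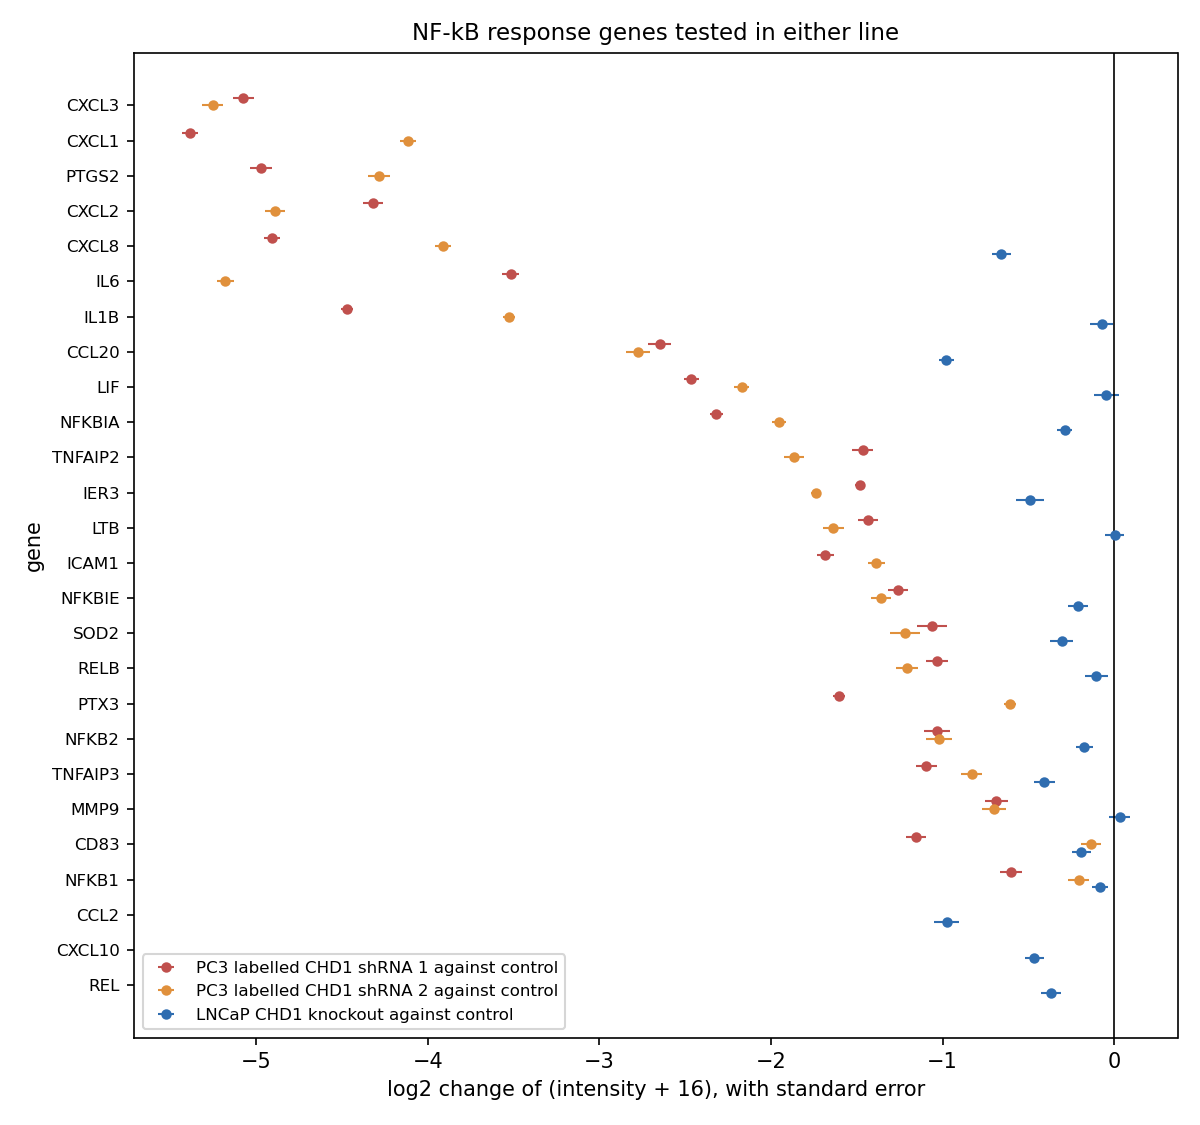
Log2 change of intensity + 16 (horizontal axis, with standard error) for each NF-kB response gene tested in either line (vertical axis), for both PC3 reagents and the LNCaP knockout against the control of their line. All 23 genes tested in PC3 lie left of 0 with either reagent, and the LNCaP changes have a median of -0.25.

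For the mean of both PC3 reagents, secreted ligands, epithelial genes and the stress response fell, but with shRNA 1 alone none of the 3 lists passed (adjusted p = 0.11, 0.16 and 0.83, against 7.4e-04, 0.0038 and 1.0e-07 with shRNA 2). With an estimated correlation the shRNA 2 calls also ended (camera adjusted p = 0.16, 0.19 and 0.16). Of 24 interleukin and growth factor ligands, 16 were lower and 4 higher, with a median of -0.41 (adjusted p = 0.012; adjusted p = 0.31 with an estimated correlation). INHBA, a subunit of activin, fell 6.65-fold and 8.04-fold, and LIF 5.52-fold and 4.50-fold. The ligand list shares IL1A, IL1B, IL6, LIF and CSF2 with the NF-kB response list, so its call is not independent of that list. Of 19 epithelial genes, 16 were lower and 3 higher, with a median of -0.47 (adjusted p = 0.013; adjusted p = 0.31 with an estimated correlation). The cadherin CDH3 fell 4.37-fold and 3.41-fold, the membrane protease ST14 4.06-fold and 3.27-fold and its inhibitor SPINT1 2.30-fold and 3.02-fold, whereas MAL2, which acts in transcytosis, rose 4.22-fold and 3.83-fold. Of 22 genes of the integrated stress response, 18 were lower for the mean of both reagents (median -0.72, adjusted p = 0.0023; adjusted p = 0.36 with an estimated correlation). DDIT4, an inhibitor of mTOR signalling, fell 2.11-fold and 9.0-fold, and the amino acid transporter SLC7A5 2.28-fold and 3.14-fold. The weakest probe sets with shRNA 1 changed by -0.05 for ST14 and -0.35 for INHBA.

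Chromatin remodellers, lineage factors, hypoxia genes and PI3K pathway genes rose for the mean of both PC3 reagents. Of 23 other remodelling ATPases and subunits, 17 were higher and 4 lower, with a median of 0.88 (adjusted p = 0.0012; adjusted p = 0.27 with an estimated correlation). The ISWI ATPases SMARCA1 and SMARCA5 rose 4.79-fold and 3.73-fold for shRNA 1 and 4.57-fold and 4.38-fold for shRNA 2, and PBRM1 rose 4.27-fold and 3.24-fold. Of 9 lineage transcription factors, 7 were higher (median 1.01, adjusted p = 0.0097; adjusted p = 0.25 with an estimated correlation). ETV1 rose 3.72-fold and 4.27-fold, SOX9 2.83-fold and 3.12-fold, the pioneer factor FOXA1 3.52-fold and 1.98-fold, NR2F1 2.39-fold and 1.54-fold, HOXB13 2.77-fold and 1.46-fold, and the glucocorticoid receptor NR3C1 3.27-fold and 2.94-fold.

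Of 23 hypoxia and glycolysis genes, 16 were higher and 5 lower in PC3 (median 0.37, adjusted p = 0.0078; adjusted p = 0.27 with an estimated correlation), but the list did not pass with shRNA 1 alone (14 higher and 7 lower, adjusted p = 0.082). The oxygen sensor EGLN1 rose 4.07-fold and 4.59-fold, the mitophagy receptor BNIP3L 4.74-fold and 3.11-fold, BNIP3 1.91-fold and 3.02-fold and GBE1, the glycogen branching enzyme, 2.72-fold and 3.91-fold. Of 19 PI3K, AKT and MTOR pathway components, 12 were higher and 4 lower (median 0.66, adjusted p = 0.0097; adjusted p = 0.27 with an estimated correlation), a call that ended when the trend on gene span was removed (median 0.52, adjusted p = 0.13, in a range of 2.4e-04 to 0.27 over the camera alternatives); most of the median stayed, so the lost call does not show that the trend made the pattern. The inhibitory kinase GSK3B, whose probe sets ranged from -0.63 to 2.45 for shRNA 1, rose 5.46-fold and 3.62-fold, FOXO3, which AKT inhibits, 4.2-fold and 2.90-fold, PIK3R3 2.59-fold and 3.17-fold and RPS6KB1, the S6 kinase, 4.31-fold and 3.23-fold. The weakest probe sets with shRNA 1 changed by 0.02 for EGLN1, -0.02 for PBRM1, 0.00 for NR3C1, 0.06 for FOXO3, 0.17 for PIK3R3, 0.24 for SMARCA1 and 0.40 for ETV1. Each of these groups moved with the 1.86-fold lower poly-A spikes of the shRNA arrays.

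Of 23 lists tested for the mean of both PC3 reagents, 9 passed, 4 up and 5 down, and 1 of them, NF-kB, also passed with an estimated correlation. Counts adjusted over the list alone equalled those over all genes for every list in this contrast. The other lists did not pass. Replication genes were lower in 19 and higher in 9 of 29 (adjusted p = 0.18), homologous recombination genes higher in 9 and lower in 3 of 16 (adjusted p = 0.10, but 0.0074 with no level filter and 0.047 with a pseudocount of 64, in a range of 0.0074 to 0.50 over the camera alternatives), chromodomain helicases higher in 6 and lower in 1 of 7 (adjusted p = 0.10) and mesenchymal genes higher in 12 and lower in 7 of 19 (adjusted p = 0.12). LNCaP line markers were higher in 5 and lower in 2 of 7 (adjusted p = 0.14), PC3 line markers higher in 4 and lower in 9 of 14 (adjusted p = 0.18) and histone genes higher in 8 and lower in 6 of 15 (adjusted p = 0.17, but 0.031 with the span trend removed, in a range of 0.031 to 0.44 over the camera alternatives). Cholesterol synthesis genes were higher in 6 and lower in 11 of 18 (adjusted p = 0.40), ribosome biogenesis genes higher in 10 and lower in 10 of 22 (adjusted p = 0.40) and androgen receptor targets higher in 7 and lower in 6 of 13 (adjusted p = 0.48). In 3 lists the median, mean and test differed in sign: interferon-stimulated genes (7 higher and 10 lower of 17, adjusted p = 0.99), p53 targets (8 higher and 12 lower of 20, adjusted p = 0.98) and unfolded protein response chaperones (6 higher and 12 lower of 19, adjusted p = 0.55). Leukocyte markers, neuroendocrine genes and fibroblast and endothelial markers had 3, 3 and 4 tested genes in PC3, too few for the test.

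The 2 PC3 reagents parted on the cell cycle. In the arrays labelled shRNA 1, all 25 G2/M and mitosis genes fell, with a median of -2.33 (adjusted p = 1.0e-10; adjusted p = 0.13 with an estimated correlation), and 26 of 29 DNA replication genes fell while 3 rose (median -1.22, adjusted p = 5.0e-06; adjusted p = 0.17 with an estimated correlation). BIRC5, the survivin gene, fell 14.0-fold, the ubiquitin-conjugating enzyme UBE2C 12.1-fold, CDK1 10.9-fold and CCNB1 8.53-fold, and of the nucleotide synthesis genes RRM2 fell 15.7-fold, TK1 8.99-fold and TYMS 6.50-fold, with UHRF1 4.41-fold lower. In the arrays labelled shRNA 2, 17 of 25 G2/M genes rose and 7 fell (median 0.44, adjusted p = 0.020; adjusted p = 0.41 with an estimated correlation), and 22 of 29 replication genes rose and 3 fell (median 0.78, adjusted p = 4.6e-05; adjusted p = 0.16 with an estimated correlation). BUB1B, a spindle checkpoint kinase, rose 3.20-fold, DLGAP5 2.90-fold, KIF23 2.77-fold and NUSAP1 2.77-fold, and CCNE2 rose 4.16-fold, MCM6 3.73-fold, POLE2 2.80-fold and MCM4 2.53-fold. Other probe sets of KIF23 and MCM4 went the other way with shRNA 2 (-0.34 and -0.06), and 1 of TYMS changed by -0.05 with shRNA 1. The integrated stress response did not pass with shRNA 1 (10 higher, 9 lower, adjusted p = 0.83) and fell in 20 of 22 genes with shRNA 2 (median -1.42, adjusted p = 1.0e-07; adjusted p = 0.16 with an estimated correlation), where TRIB3 fell 7.25-fold, CEBPB 3.17-fold and PHGDH, of serine synthesis, 3.14-fold. For the mean of both reagents, 19 of 25 G2/M genes were lower and 3 higher (median -1.01, adjusted p = 2.4e-04; adjusted p = 0.27 with an estimated correlation), and CDC20 fell 15-fold with shRNA 1 and 1.41-fold with shRNA 2.

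**Figure D4:**
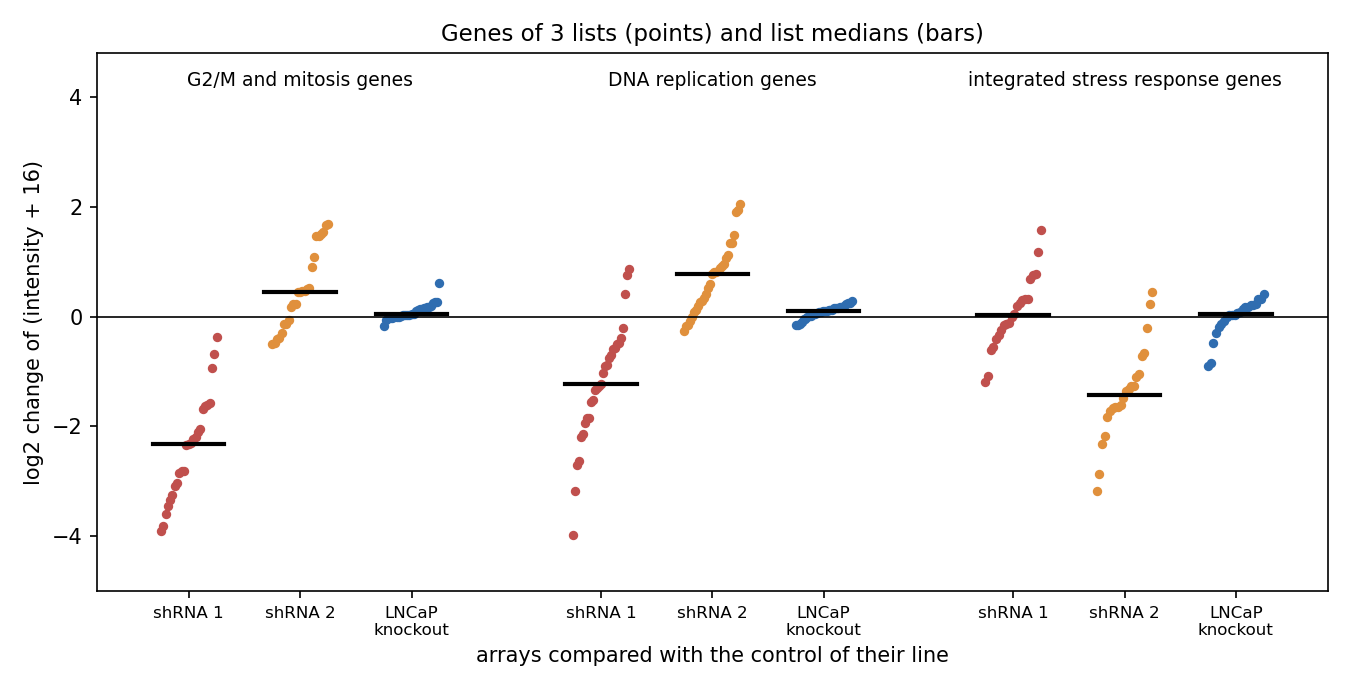
Log2 change of intensity + 16 (vertical axis) of each tested gene (points) in 3 gene lists against the control of its line, with the list median as a bar, for the PC3 arrays labelled shRNA 1 and shRNA 2 and the LNCaP knockout (horizontal axis). The G2/M medians are -2.33, 0.44 and 0.04, and those of replication genes -1.22, 0.78 and 0.10.

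Other lists with shRNA 2 alone also passed. Homologous recombination genes were higher in 12 and lower in 2 of 16 (adjusted p = 0.0058; adjusted p = 0.16 with an estimated correlation), with FANCI 3.23-fold, BARD1 2.56-fold, EXO1 2.36-fold and NBN 2.30-fold higher. Histone genes were higher in 11 and lower in 2 of 15 (adjusted p = 0.020; adjusted p = 0.20 with an estimated correlation): H2AZ2, whose probe sets ranged from -0.36 to 1.84, rose 3.59-fold, H2BC4 3.02-fold and H2BC12 2.14-fold, while the linker histone H1-10 fell 3.22-fold. Chromodomain helicases were higher in 6 of 7 (adjusted p = 0.047; adjusted p = 0.28 with an estimated correlation), with CHD6 2.18-fold, CHD8 1.85-fold and CHD1L 1.37-fold higher. Hypoxia genes (adjusted p = 0.0037; adjusted p = 0.16 with an estimated correlation) included PDK1, which inhibits pyruvate dehydrogenase and rose 5.05-fold. The lowest log2 changes among probe sets were -0.09 for PDK1, -0.07 for NBN and CHD1L, -0.06 for CHD6, 0.09 for FANCI and 0.16 for BARD1. Epithelial genes (adjusted p = 0.0038; adjusted p = 0.19 with an estimated correlation) included ELF3 and SPINT2, which fell 4.44-fold and 1.98-fold. PI3K components passed at an adjusted p of 0.016 (adjusted p = 0.20 with an estimated correlation), among them EIF4EBP1, a translation inhibitor, which fell 2.13-fold. The tests were passed by 6 of 23 lists for shRNA 1 and 13 of 23 for shRNA 2, in each case 1 with an estimated correlation. For the lists that passed with either reagent or between them, counts adjusted over the list alone equalled those over all genes, except that 2 lineage factors rather than 1 were lower with shRNA 2. With shRNA 1, PI3K components (adjusted p = 0.011), other remodellers (adjusted p = 0.0028) and lineage factors (adjusted p = 0.0099) passed, with adjusted p = 0.24, 0.22 and 0.14 with an estimated correlation.

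Compared directly, the arrays labelled shRNA 2 exceeded those labelled shRNA 1 in proliferation genes. RRM2, a subunit of ribonucleotide reductase, stood at 1995 ± 49.3 (SD, n = 3) against 59.0 ± 4.98, 26.8-fold higher on the tested scale. PCLAF, which binds PCNA, was 15.3-fold, CDK1 15-fold and ANLN, of the cytokinetic ring, 14.6-fold higher. The mucosal peptide TFF2 was 10.6-fold, the calcium-binding protein S100P 11.2-fold, the urea transporter SLC14A1 8.42-fold and the stress cytokine GDF15 7.53-fold lower. Against the control, the probe sets of GDF15 ranged from -3.06 to -0.27 with shRNA 2 and from -0.19 to -0.09 with shRNA 1. All 25 G2/M genes (median 3.01, adjusted p = 3.9e-21; adjusted p = 0.027 with an estimated correlation) and all 29 replication genes (median 1.73, adjusted p = 4.6e-19; adjusted p = 0.027 with an estimated correlation) were higher, and all 22 stress response genes were lower (median -1.38, adjusted p = 4.6e-15; adjusted p = 0.10 with an estimated correlation). CHD1 was 1.16-fold lower (adjusted p = 0.0078). Limma called 7715 of 11865 genes, 3923 higher and 3792 lower. The poly-A spikes differed by 0.0008 log2 between these groups, with an exact permutation p of 1. The hybridisation spikes differed by -0.09, the ACTB 3'-to-5' log2 ratio by -0.10 and the GAPDH ratio by 0.05, each with an exact permutation p of 0.1, the smallest that 20 splits can give (0.191 after Benjamini-Hochberg).

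Of 23 lists in this direct comparison of the reagents, 8 passed. The others besides those named were interferon-stimulated genes (12 higher and 1 lower of 17, adjusted p = 0.0097; adjusted p = 0.20 with an estimated correlation), cholesterol synthesis (14 higher and 2 lower of 18, adjusted p = 0.011; adjusted p = 0.17 with an estimated correlation) and homologous recombination (10 higher and 2 lower of 16, adjusted p = 0.015; adjusted p = 0.20 with an estimated correlation). Lower were the unfolded protein response chaperones (13 lower and 6 higher of 19, adjusted p = 0.022; adjusted p = 0.28 with an estimated correlation) and LNCaP line markers (6 of 7, adjusted p = 0.0097; adjusted p = 0.10 with an estimated correlation).

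The LNCaP comparison asked the same of a CHD1 knockout, and its changes were smaller. RND3 rose from 128 ± 6.70 (SD, n = 3) to 858 ± 4.90, 6.09-fold on the tested scale. SYT4, a vesicle protein, rose 4.63-fold, the gap junction gene GJA1 3.48-fold, CRISP3 3.38-fold, CDK6, a kinase of the G1 phase, 2.78-fold, and AGR2, a disulphide isomerase of secretory cells, 2.54-fold. SEMA6D (2.73-fold), NAV2 (2.41-fold), FCGBP (2.37-fold), DHRS2 (2.36-fold), PIGR (2.31-fold) and TM4SF1 (2.27-fold) completed the 12 largest rises. The weakest probe sets changed by -0.03 for CDK6, -0.04 for NAV2, 0.02 for TM4SF1 and 0.10 for SEMA6D. TMEFF2, a prostate transmembrane protein, fell from 1224 ± 33.8 to 36.2 ± 12, 24.2-fold on the tested scale. However, another of its probe sets changed by -0.05, and the call ended without probe sets ending in _x_at or _s_at (limma adjusted p = 0.81, in a range of 2.5e-22 to 0.81). The imprinted gene PEG10 fell from 179 ± 7.47 to 5.25 ± 1.13 (9.16-fold on the tested scale, but -0.87 in log2 by its other probe set). Its neighbour SGCE fell 4.24-fold. MAGEA4 fell 5.98-fold, LAPTM4B 4.94-fold, TFPI, an inhibitor of clotting whose probe sets ranged from -2.26 to -0.05, 4.8-fold and ZNF518B 4.79-fold.

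The remaining 5 of the 12 largest falls in LNCaP were genes on the Y chromosome, of which 8 of 10 tested were lower and 7 at least 2-fold. Limma called 4776 of 11865 genes, 2567 higher and 2209 lower. At a fold of at least 2, 18 were higher and 58 lower. With each array centred on its median, a scaling added after the data were seen, the split of the calls moved from 53.7% higher to 3425 higher and 1724 lower. The median change of all genes was 0.01. No separate knockout clones are named in the labels, so an effect of CHD1 loss on any gene cannot be told apart from a difference of subclone.

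Hypoxia and glycolysis genes fell in the LNCaP knockout, along with NF-kB and interferon response genes. Of 23 hypoxia genes, 17 were lower and 0 higher, with a median of -0.29 (adjusted p = 9.0e-08; adjusted p = 0.54 with an estimated correlation). The histone demethylase KDM3A fell 1.87-fold (0.00 by its other probe set), and the glycolytic enzymes ENO1, PGK1 and LDHA fell 1.30-fold, 1.22-fold and 1.17-fold. Of 18 NF-kB response genes, 12 were lower and 0 higher (median -0.25, adjusted p = 1.6e-05; adjusted p = 0.30 with an estimated correlation). The chemokines CCL20 and CCL2 both fell 1.97-fold, CXCL8 1.58-fold and CXCL10 1.38-fold. IER3 fell 1.41-fold (SE 0.08 on the log2 scale), the NF-kB inhibitors TNFAIP3 and NFKBIA 1.33-fold and 1.22-fold and the NF-kB subunit REL 1.29-fold; other probe sets of NFKBIA and REL changed by 0.02 and 0.05. Of 20 interferon-stimulated genes, 9 were lower and 1 higher (10 lower adjusted over the list alone), with a median of -0.17 (adjusted p = 0.0047; adjusted p = 0.43 with an estimated correlation): IFIT2 fell 1.84-fold, OASL 1.67-fold, IFIT1 1.54-fold and IFI44 1.35-fold (-0.08 by its other probe set).

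Ribosome biogenesis and cell cycle genes rose slightly in the knockout. Of 22 ribosome biogenesis genes, 13 were higher and 0 lower (14 higher adjusted over the list alone), with a median of 0.15 (adjusted p = 7.4e-04; adjusted p = 0.62 with an estimated correlation); UTP20 rose 1.27-fold, RRP1B 1.17-fold, the methyltransferase FBL 1.12-fold and NOLC1 1.12-fold. The call of RRP1B, whose probe sets ranged from -0.04 to 0.23, ended with the mean of its probe sets (0.09, adjusted p = 0.12, in a range of 3.6e-06 to 0.12 over the alternatives). Of 30 replication genes, 16 were higher and 3 lower (median 0.10, adjusted p = 0.016; adjusted p = 0.64 with an estimated correlation), with RRM1 and GINS1 1.18-fold and TYMS 1.12-fold higher and RFC3 1.11-fold lower. Probe sets of TYMS and RFC3 ranged from 0.02 to 0.22 and from -0.14 to 0.30, and with the mean of its probe sets RFC3 reversed to 0.02 (adjusted p = 0.59, in a range of 2.2e-04 to 0.59). Of 27 G2/M genes, 10 were higher and 1 lower (median 0.04, adjusted p = 0.037; adjusted p = 0.62 with an estimated correlation). The mitotic kinase AURKA rose 1.53-fold, UBE2C 1.20-fold and NDC80 1.19-fold, while CDK1 fell 1.12-fold. Both cell cycle calls ended without control replicate 1 (adjusted p = 0.12 for G2/M and 0.056 for replication) and with quantile normalisation (adjusted p = 0.16 and 0.086), within ranges of 0.0083 to 0.62 and 0.0010 to 0.64 over all alternatives. The G2/M call also ended with the span trend removed (adjusted p = 0.055).

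Histones, chromodomain helicases and neuroendocrine genes fell in LNCaP. Of 14 histone genes, 8 were lower and 2 higher (median -0.19, adjusted p = 0.015; adjusted p = 0.30 with an estimated correlation), with H4C8 1.90-fold, H1-2 1.48-fold and H2AC6 1.47-fold lower and H2AJ 1.63-fold higher. Of 8 other chromodomain helicases, 6 were lower and 1 higher (median -0.20, adjusted p = 0.023; adjusted p = 0.30 with an estimated correlation): CHD3 fell 1.51-fold (adjusted p = 0.052 without probe sets ending in _x_at or _s_at, in a range of 1.4e-09 to 0.052), CHD4 1.19-fold and CHD9 1.17-fold, and CHD7 rose 1.24-fold. The weakest probe sets changed by 0.11 for CHD9, 0.00 for CHD7 and 0.05 for H2AJ. Of 5 neuroendocrine genes, 3 were lower and 0 higher (4 lower adjusted over the list alone; median -0.23, adjusted p = 0.013; adjusted p = 0.30 with an estimated correlation). DDC, which makes dopamine and serotonin from their precursors, fell 2.59-fold from 1304 ± 20.6 to 494 ± 6.64 (0.00 by its other probe set), ENO2 fell 1.30-fold and ONECUT2 1.17-fold, a call that ended with the mean of its probe sets (-0.08, adjusted p = 0.051, in a range of 0.0016 to 0.051); SYP was 1.13-fold lower (adjusted p = 0.060, in a range of 0.0077 to 0.20 over the alternatives). The neuroendocrine call ended with no level filter (median -0.01, adjusted p = 0.16, in a range of 0.0046 to 0.30 over the camera alternatives).

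Of 24 lists tested in LNCaP, 9 passed, 3 up and 6 down, and 0 passed with an estimated correlation; fry called 16. Counts adjusted over the list alone are given where they differ. Lists that did not pass were the secreted ligands (0 higher and 3 lower of 12, adjusted p = 0.053, though they passed under 6 camera alternatives at 0.031 to 0.046, in a range of 0.031 to 0.48), cholesterol synthesis (8 higher and 2 lower of 19, adjusted p = 0.10, but 0.025 with the mean of probe sets and 0.036 with no level filter, in a range of 0.025 to 0.48), fibroblast and endothelial markers (0 higher and 2 lower of 6, adjusted p = 0.15) and homologous recombination (6 higher and 2 lower of 20, 7 higher adjusted over the list alone, adjusted p = 0.24). At an adjusted p of 0.60 stood TNF and NF-kB signalling components (5 higher and 7 lower of 22), androgen receptor targets (8 higher and 6 lower of 17), p53 targets (4 higher and 4 lower of 21), mesenchymal genes (2 higher and 2 lower of 7), LNCaP line markers (3 higher and 5 lower of 12), the integrated stress response (9 higher and 6 lower of 22) and the unfolded protein response (4 higher and 6 lower of 19). Epithelial genes (6 higher and 6 lower of 18, adjusted p = 0.63), lineage factors (1 higher and 3 lower of 8, adjusted p = 0.66), other remodellers (4 higher and 5 lower of 23, adjusted p = 0.70) and PI3K components (3 higher and 2 lower of 20, 1 lower adjusted over the list alone, adjusted p = 0.98) also failed. The median, mean and test differed in sign for the stress response, unfolded protein response, PI3K, remodeller and lineage lists. Leukocyte and PC3 line markers had 2 tested genes each, too few for the test.

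Between the lines, the changes were mostly unrelated. Across 10686 genes, which are not independent replicates, the PC3 and LNCaP changes correlated at -0.026 (Spearman -0.011), and 49.1% had the same sign. Genes changed the same way under both PC3 reagents and in the knockout numbered 1422, of which 770 were higher and 652 lower, and 1532 went in opposite directions. Higher genes overlapped more than independent lists would (691 by n1 × n2 / N; odds ratio 1.22, 95% interval 1.11 to 1.35, Fisher's exact p = 6.4e-05) and lower genes less (730 by the same product; odds ratio 0.81, interval 0.73 to 0.90, Fisher's exact p = 5.5e-05). Fisher's test treats the genes as independent, so its p-values and intervals do not measure the spread between arrays. CDK6 rose 3.15-fold with either PC3 reagent and 2.78-fold in LNCaP. KITLG, the KIT ligand, rose 3.60-fold, 4.71-fold and 1.69-fold, ITPR1, a calcium channel of the endoplasmic reticulum, 2.47-fold, 7.48-fold and 1.61-fold, MTARC1 2.23-fold, 4.2-fold and 1.95-fold, NAV2 1.81-fold, 2.44-fold and 2.41-fold and SH3BGRL 1.61-fold, 1.62-fold and 1.68-fold. Other probe sets of some of these went the other way: the lowest log2 changes with shRNA 1, with shRNA 2 and in LNCaP were -0.14, -0.06 and -0.03 for CDK6, -0.03, -0.04 and -0.02 for KITLG, -0.07, -0.06 and 0.00 for ITPR1 and -0.11, -0.12 and -0.04 for NAV2. SYNGR3 fell 2.47-fold, 2.90-fold and 3.64-fold, PROCR, the protein C receptor, 3.61-fold, 1.99-fold and 2.29-fold, CCL20 6.27-fold, 6.85-fold and 1.97-fold, TNNT1 1.85-fold, 2.25-fold and 1.88-fold, LOC100996740 1.99-fold, 1.88-fold and 2.75-fold and MAFF, a small MAF protein, 1.73-fold, 2.60-fold and 1.93-fold.

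The interaction test compared the knockout change in LNCaP with the mean change in PC3. The line goes together with the kind of reagent, with the measured size of the CHD1 change and with the poly-A spike difference found in PC3. Any difference of subclone between the knockout and control LNCaP cells also goes with it. The test does not part the lines from these. LCN2, S100A9 and C3 fell in PC3 and rose in LNCaP by 1.57-fold, 1.45-fold and 1.15-fold. IL1B fell in PC3 and changed by -0.07 (adjusted p = 0.44) in LNCaP. In the other direction, PEG10 rose 4.31-fold and 5.16-fold in PC3, the phosphatase CDC14B 4.77-fold and 4.34-fold, the muscarinic receptor CHRM3 5.25-fold and 4.53-fold and ZNF518B 4.0-fold and 2.18-fold, while in LNCaP PEG10 fell 9.16-fold, CDC14B 3.52-fold, CHRM3 3.15-fold and ZNF518B 4.79-fold. Probe sets disagreed, ranging in LNCaP from -1.82 to 0.07 for CDC14B, from -1.65 to 0.01 for CHRM3 and from -2.26 to -0.10 for ZNF518B, and with shRNA 1 from -0.06 to 2.25, -0.09 to 2.39 and -0.14 to 2.00. Those of PEG10 ranged from -3.20 to -0.87 in LNCaP. CHD1 fell more in LNCaP than in PC3 (adjusted p = 1.8e-10). Limma called 8447 of 10686 genes, 4835 higher and 3612 lower in LNCaP relative to PC3, with a median of 0.11 over all genes. The lines were fitted from arrays that appear to be normalised separately, so only changes within a line enter this contrast.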

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

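The tests of spike-ins, of the ACTB ratio and of the Y-linked genes, the correction for gene span and the list tests between the lines were chosen only after the results they bear on were seen.

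The change in the LNCaP knockout and the mean change in the PC3 arrays labelled CHD1 shRNA differed for many genes by the limma interaction test. It called 8447 genes, and of 100 splits of the arrays 1, the real one, gave as many (highest other 2912). The splits shuffled the arrays within both lines, which also removes the change within each line. They therefore cannot test whether the changes of the lines differ. On the log2 scale, the LNCaP change less the PC3 mean change was -0.89 for CHD1. It was 6.35 for LCN2, 5.68 for S100A9, 4.10 for C3 and 3.93 for IL1B, which fell in PC3, and -5.43 for PEG10, -4.00 for CDC14B, -3.94 for CHRM3 and -3.82 for ZNF518B, which rose in PC3 and fell in LNCaP.

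Of 22 gene lists tested for the same difference, 10 passed, 5 in each direction, and 0 passed with an estimated correlation; fry called 19. NF-kB response genes had a median difference of 1.10, with 15 of 15 higher in LNCaP relative to PC3 (camera adjusted p = 1.1e-05, and 0.11 with an estimated correlation). The list was lower in both lines, with a median of -1.61 in PC3 and -0.25 in LNCaP, so the difference is a smaller fall in LNCaP. For G2/M genes the median difference was 1.29, with 19 of 25 higher and 2 lower (camera adjusted p = 1.1e-05, and 0.20 with an estimated correlation). Against the control of each line, however, their median was -2.33 with shRNA 1, 0.44 with shRNA 2 and 0.04 in LNCaP. The LNCaP median thus lay between those of the 2 reagents, which the PC3 mean hides. Stress response genes had a median difference of 0.70, with 17 of 22 higher and 3 lower (camera adjusted p = 0.0028, and 0.23 with an estimated correlation). Their medians against control were 0.02 with shRNA 1, -1.42 with shRNA 2 and 0.05 in LNCaP. LNCaP thus lay apart from shRNA 2 and close to shRNA 1. Epithelial genes had a median difference of 0.43, with 14 of 17 higher and 3 lower (camera adjusted p = 0.037, and 0.28 with an estimated correlation). For ligands it was 0.34, with 9 of 12 higher and 0 lower (camera adjusted p = 0.035, and 0.20 with an estimated correlation). The ligand list shares members with the NF-kB list.

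The remaining 5 lists were lower in LNCaP relative to PC3. Hypoxia genes had a median difference of -0.66, with 18 of 22 lower and 3 higher (adjusted p = 9.4e-05; adjusted p = 0.32 with an estimated correlation), and PI3K components -0.94, with 12 of 18 lower and 4 higher (adjusted p = 0.0072; adjusted p = 0.20 with an estimated correlation). Other chromatin remodellers had -0.88, with 16 of 22 lower and 3 higher, or 4 higher adjusted over the list alone (adjusted p = 0.0015; adjusted p = 0.18 with an estimated correlation). Chromodomain helicases had -0.78, with 6 of 7 lower (adjusted p = 0.020; adjusted p = 0.20 with an estimated correlation), and lineage factors -1.18, with 6 of 8 lower and 2 higher (adjusted p = 0.027; adjusted p = 0.20 with an estimated correlation).

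Most tested genes differed between the PC3 control arrays and both groups labelled CHD1 shRNA. RNA degraded from the 5' end in the control would raise its ACTB 3'-to-5' log2 ratio, which was 0.00426 above that of the shRNA arrays, well within the replicate SD of 0.0439. A trend on gene span is argued against as the whole cause, since 7177 genes changed the same way under both reagents with it removed, 92.1% of the number before. A separate preparation of the control arrays remains open: the poly-A spikes differed by -0.89, or -6.34 replicate SDs, and every control array lies on one side, so the design cannot part preparation from the reagents. An effect common to both reagents, CHD1 loss included, may account for the pattern and was not separated from this.

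NF-kB response genes were lower in the PC3 arrays of both reagents. With the span trend removed, their median was -1.47 (adjusted p = 7.5e-11, in a range of 3.2e-11 to 0.028 over the camera alternatives), which argues against that trend as the cause. An effect that depends only on signal level and span is argued against too, since 0% of 10000 random lists matched on both had a median as low, the lowest being -0.62 against -1.61. A separate preparation or culture of the control cells remains open, as for the broad pattern. A loss of NF-kB signalling after CHD1 knockdown may be a biological explanation. In the arrays labelled shRNA 1, however, CHD1 was not lower in the main setting and changed by -0.279 with the span trend removed. This explanation was therefore not tested independently of the labels.

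Genes on the Y chromosome were lower in the LNCaP knockout: limma called 8 of 10 lower, with a median of -2.62 among those. A cell line as unlike LNCaP as PC3 is argued against in the knockout arrays. The lowest correlation of a knockout with a control array was 0.994, and the highest between the lines 0.876. A line closely related to LNCaP may correlate as highly, so the correlation cannot exclude it. Loss of the chromosome in the knockout cells may account for the pattern: all 4 Y-linked genes with a control intensity over 100 were lower, but genes near background cannot show it. Outgrowth of a subclone during editing and an effect of CHD1 loss cannot be told apart, since no separate knockout clones are named in the labels.

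Other splits of the arrays were counted for each result. Of 100 splits of the PC3 arrays, 1 gave 7793 genes changed the same way under both reagents (highest other 2170), and 1 gave 10289 for their mean (highest other 4199). For both counts this excludes only chance spread between single arrays. Where the replicates of a group share a culture or preparation, the splits cannot exclude differences between cultures or preparations. For the 1422 genes shared with LNCaP, 1 of 100 splits gave as many (highest other 374), but shuffled arrays give fewer calls in each line, so this says nothing of the overlap; independent lists would share 691 higher and 730 lower genes. For the 9 lists shifted in PC3, 26 of 100 splits gave as many and the highest other gave 13, so chance is not excluded for that number. Splits of 3 arrays against 3 number 10 and cannot give a share under 0.05: the counts were 9980, 9851, 7715 and 4776 for the reagents, their comparison and the knockout, with 0 as the highest other, and 9 lists in LNCaP with 7 as the highest other.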

How the results depend on the processing

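The minimum fold of 2, the centring of arrays on their median and the correction for gene span were chosen only after the results were seen. Of 273 values of the results that answer a comparison, 254 kept their direction and side of the threshold, or stayed within 1.5 times; so did 745 of 816 list values and 5082 of 5099 values of named genes. Of the other list values, 18 reversed, 29 gained and 24 lost a call; of the named genes, 7, 5 and 5. Signal near background limits the precision for dim genes, CHD1 in PC3 among them, and the cause of a change was not tested unless named.

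The CHD1 change with shRNA 1 reversed to 0.0071 with quantile normalisation and 0.0764 with the mean of probe sets, ranged from -0.040 to 0.027 with 1 array left out (above 0 without control replicate 1 or 2 or shRNA 1 replicate 1), and reached -0.279 with the span trend removed (adjusted p = 9.0e-04, in a range of 9.0e-04 to 0.99). The difference between the lines called 5580 genes at the 60th percentile, where fewer genes were tested. With an estimated correlation 1 list passed in PC3 and 0 in LNCaP; with fry, 20 and 16. A fold of at least 2 left 2340 and 1843 genes for the reagents, 1867 for their mean, 689 between them, 76 in LNCaP, 1766 between the lines, 1278 under both reagents and 2 in both lines, CDK6 and SYNGR3; a stricter limit can only lower a count.

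In several uncalled lists the direction of the list test reversed; the values are medians, which need not change sign with it. Interferon genes in PC3 had -0.222 with a pseudocount of 1, -0.279 with quantile normalisation and -0.199 to -0.195 in the 3 of 9 runs with 1 array left out that reversed (-0.203 to -0.157 over all 9). The mean of probe sets gave -0.176 for p53 targets in PC3 and, in LNCaP, 0.0515 for androgen receptor targets and 0.0178 for PI3K components; PI3K in LNCaP also had 0.0459 with arrays centred, 0.0205 with the span trend removed and 0.0173 to 0.0195 in the 3 of 6 runs with 1 array left out that reversed (0.00049 to 0.0195 over all 6). Fry gave -0.178 and -0.0081 for the unfolded protein response in PC3 and LNCaP. With the span trend removed, androgen receptor targets in PC3 had -0.0917, the unfolded protein response 0.0668 and remodellers in LNCaP 0.0278. Among genes, RFC3 in LNCaP reversed to 0.0228 with the mean of probe sets. Without probe sets ending in _x_at or _s_at, MSI2 with shRNA 1 went to -0.455 and BIRC5 and CCNB1 with shRNA 2 to 0.138 and 0.254. With the span trend removed, BIRC5 and UBE2C with shRNA 2 went to 0.0779 and 0.185 and CEBPB with shRNA 1 to 0.0629.

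With 1 array left out, counts ranged from 9553 to 10035 for shRNA 1, 9384 to 9926 for shRNA 2, 9827 to 10228 for their mean, 7221 to 8001 between them, 7430 to 7935 under both, 4046 to 4853 in LNCaP, 8198 to 8537 between the lines and 1184 to 1435 in both lines. CHD1 ranged from -0.280 to -0.167 with shRNA 2 and from -1.03 to -0.98 in LNCaP, and lists from 9 to 9 in PC3 and 7 to 10 in LNCaP. Over all alternatives the CHD1 ranges were wider. They were -0.478 to -0.104 with shRNA 2 (limma adjusted p = 2.4e-06 to 0.041) and -1.13 to -0.75 in LNCaP. The replicate numbers do not pair the arrays: 2 of 12 pairs correlated above 0.1 (-0.118 to 0.112), and 2 arrays matched their own number best. With the replicate number as a replicate block, the counts were 9959, 9837, 10257, 7665, 7778, 4602, 8384 and 1354, and lists 9 and 10; besides the ligand list and SYP in LNCaP, which gained calls (adjusted p = 0.046 and 0.0499), no other list or named gene changed its call.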

Other observations

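The trends on gene span and chromosome and the test of neighbouring genes were looked at only after the results were seen.

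Long genes rose relative to short genes in PC3. The median change of all genes was -0.12 for the mean of both reagents, and the scaling steps are not given. A fall of short genes therefore cannot be read as absolute. Among the 2964 tested genes with the longest annotated span, 830 rose and 43 fell at least 2-fold for the mean of both reagents, with a median of 0.36, and among the 2967 with the shortest 75 rose and 149 fell, with a median of -0.26. Across genes, which are not independent replicates, Spearman's correlation of change and span was 0.361 for either reagent and -0.088 between them. In LNCaP it ran the other way at -0.106: 18.8% of the 2964 longest genes rose and 25.6% fell, against 24.3% and 14.2% of the 2964 shortest.

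Changes in the LNCaP knockout were uneven over the chromosomes. On chromosome 13, 28 of 193 tested genes rose and 86 fell, with a median of -0.06, while on chromosome 20, 118 of 350 rose and 41 fell, with a median of 0.04. These 2 chromosomes were singled out after the values were seen, and no test of their difference from the others was run. Of 51 genes outside the Y chromosome that fell at least 2-fold, PEG10 formed adjacent pairs with both SGCE and PPP1R9A, which fell by 2.08 and 1.57 on the log2 scale. Of 10000 random sets of 51 tested genes, 181 had at least 2 adjacent pairs, with a mean of 0.214 and a highest of 3.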
